A study of Chelon labrosus with 24 samples.

How the data were processed

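Liver RNA of immature thicklip grey mullets (Chelon labrosus) held in cages at 2 places in a polluted harbour was measured on 24 one-colour arrays. Total RNA was extracted with Trizol and cleaned on a silica column, and it was copied from an oligo-dT-T7 primer and labelled with Cy3, per the labels' protocols. The arrays carry custom probes, and each gene is named only as the array design spells it. The gene description column of the scanner files is empty, so an abbreviation without a settled meaning is given as spelled. No genome coordinates are printed, because the probes carry none.

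The spot intensity values were made by the authors' scanner software, Agilent Feature Extraction 9.5.3.1, per the file headers. It subtracted background, removed spatial and multiplicative trends within each array and put surrogate values in place of the dimmest spots, per the file headers. No step between arrays is recorded there. A second table deposited by the authors holds log2 values of the same arrays. Each of its 24 columns matched its own array best, with r of 0.992 or more against that array's log2 signal. The column medians ran from 6.774 to 6.818, and the sorted columns differed by a mean SD of 0.0251. The log2 scale of that table is therefore settled by the data, while its normalization method and any centring are not given in the sources used here. It served as an alternative.

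Each array has 3148 features, of which 2612 are spots of 638 probes and the rest are controls. Spotting was 4 times for 628 probes and 10 times for 10 probes. The probes carry 166 gene names, or 160 genes after different spellings of 1 gene were joined. Spots marked by the scanner software as uneven or as population outliers (40 to 125 per array) were left out, and no spot was saturated. The log2 signals of the remaining spots of a probe were averaged, and the array's 75th percentile was subtracted. All levels below are on that scale. A probe was tested where at least 50% of its spots were well above background on at least 6 of the 24 arrays. This kept 476 probes in 129 genes and left out 162 probes. 363 probes were well above background on every array and 109 on none. Per array, 371 to 484 probes were well above background, with a median of 456.5, and the 75th percentile of the log2 signal ran from 10.7 to 12.1. The number of arrays limits the precision: the median standard error of a difference between 2 groups was 0.25 log2 units.

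One limma model (limma 3.58.1 in R 4.3.3) with a coefficient per group was fitted to all 24 arrays, so that the 4 groups of 6 share one estimate of the spread. The contrasts were inner minus outer harbour at each sampling and as the mean of both, second minus first sampling at each site, and the change of the site difference between samplings. A probe was called at a Benjamini-Hochberg adjusted p under 0.05 (limma's moderated test, two-sided). A fold change printed for a gene comes from the log2 difference. Where a probe was not well above background on any array of the dimmer group, the fold is a lower bound for the group means. It is set against the higher of each array's lowest signal well above background and the probe's own. The spread between fish is not part of it.

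The genes named below follow a rule written before the data were examined. Up to 15 genes per direction with the largest changes among called probes are named, with 1 probe per gene. CYP1A, vitellogenin, metallothionein, catalase, GST, HSP70 and choriogenin are also reported in the site contrasts, whatever their p. Where such a gene was not called, the brightest tested probe is given with the range over all its tested probes. The rule was read as the brightest of a gene's called probes, and this reading was settled after values had been seen. Where not all probes of a named gene were called, the text gives how many were.

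20 gene lists (pathways and markers of other cells) were fixed before the data were examined, with limma's camera test at a preset correlation of 0.01 for lists with 5 or more tested genes. For these lists a gene is represented by its brightest tested probe. Only 8 lists were long enough, giving 32 tests over both site contrasts and both sampling contrasts. Spellings that the fixed name patterns missed were matched to the lists by hand after the results had been seen. Among these are CYP_2 and UGT, the 2 genes with the strongest calls at the second sampling, so the lists holding them are not independent of that result. The count of list members past the threshold is given over all probes tested and adjusted over the list alone. The correlation of the site differences at both samplings was set beside all 853776 relabelings of site within sampling (exact permutation test, two-sided).

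The 24 arrays lie on 3 slides of 8, with 2 arrays of each group on every slide, and the scan day follows the slide. The first sampling fills 1 row of every slide and the second sampling the other row, so sampling and array row cannot be told apart. The sites lie in different columns, and their columns are exchanged on 1 slide. Slide was tested as a block and the site contrasts also within each slide. Alternatives chosen beforehand were 6 other scalings or backgrounds (quantile, array median, the 75th percentile over probes detected everywhere, spike-in probes, normexp with an offset of 50, and the deposited log2 values), 2 filters on dim probes, the slide, the sample number as a block, array weights, only the groups compared, a fold threshold of 1.5 and each array left out. A seventh scaling (the median over probes detected on all arrays), the level of trypsin as a covariate and lists from name patterns alone were added after the data had been seen.

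The model was tested on simulated data shaped as the site contrast of the second sampling with 476 probes. Of the probes of 10 genes changed by 0.5, 1 and 2 log2 units, 20.7%, 76.9% and 87.9% were recovered over 20 runs, and 4.01% of the calls were false. The simulated changes were balanced between up and down, and the genes varied independently with normal noise. These rates therefore do not cover the effect of array scaling on a one-sided split or of genes that vary together. Figures were drawn with matplotlib 3.10.9.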

Results

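The study used caged thicklip grey mullets, a coastal fish, as sentinels of pollution in a harbour (Pasaia). Liver gene expression was measured in fish from an inner and an outer part of the harbour at a first and a second sampling, with 6 fish in each of the 4 groups. The sample labels give day 5 and day 21 for the samplings, while the series text speaks of 3 and 15 days of exposure, so the samplings are called first and second here. The labels number the liver samples and do not state outright that each came from a separate fish. They are called fish below, and the p-values measure the spread between these samples. Each site is known only by its own caged fish, so the effect of a cage cannot be told apart from that of its site. Arrays of 1 group correlated with r between 0.925 and 0.991 across probes, which are not independent replicates. The groups had means of 465 (inner, first), 471 (outer, first), 448 (inner, second) and 428 (outer, second) probes well above background. The first principal component held 26.7% of the variance and went with sampling (r squared 0.691) far more than with site (0.0742) or slide (0.0160). At the first sampling it nonetheless parted the sites, from -20.3 to -7.35 in inner and from -6.07 to 2.63 in outer fish. At the second the sites overlapped on it (3.28 to 12.9 and 5.04 to 10.5).

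The comparison of sites at the first sampling asks how livers from the inner harbour differed from those of the outer harbour early in the caging. Heme oxygenase (Heme_oxigenase32), which breaks down heme and is induced by oxidative stress and metals, was 9.06-fold higher in the inner harbour (log2 difference 3.18 ± 0.44, SE, n = 6 and 6, adjusted p = 3.66e-05). All 6 inner fish lay above all 6 outer fish. Choriogenin L (Choriogenina_L), an egg envelope protein made by the fish liver under estrogen, was also higher (adjusted p = 0.0232), with all 4 probes called. It was well above background in 5 of 6 inner and 2 of 6 outer fish, so the size of the difference is not resolved. The inner group's SD was 3.39 log2 units, against 1.19 (outer, first), 0.89 (inner, second) and 1.52 (outer, second). The call therefore leans on a spread shared with groups that varied less. The other 3 tested genes of the estrogen responsive list (VgC and receptors ERalpha and ERb) did not pass. Alpha-2-macroglobulin, a plasma protease inhibitor, was lower in the inner harbour (-0.98 ± 0.18, adjusted p = 0.00106), again with no overlap between the groups.

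Genes of acute phase, complement and innate immunity that were called at the first sampling were all lower in the inner harbour. Of 9 tested genes of that list 3 fell, 0 rose and 6 did not pass, with 4 past when adjusted over the list alone. The 3 were alpha-2-macroglobulin, an immunoglobulin (-1.29 ± 0.39, 1 of 2 probes called) and MHC_II (adjusted p = 0.0322, 2 of 4 probes called). MHC_II was well above background in 1 of 6 inner and in 6 of 6 outer fish, so its size is not resolved. Haptoglobin had -1.13 ± 0.45 (adjusted p = 0.0878). The list as a whole did not pass (camera adjusted p = 0.145, and adjusted p = 0.561 with an estimated correlation). Of 3 heat shock genes, all with a lower mean in the inner harbour, 1 passed over all probes and 3 when adjusted over the list alone. HSC70 had -0.75 ± 0.24 (3 of 4 probes called), HSP70 -0.60 ± 0.21 on its brightest probe and HSP90 -0.62 ± 0.23, and 2 of 4 HSP70 probes were called. Transferrin, the iron carrier of plasma, fell by 0.94 (SE 0.26, adjusted p = 0.0249), the only 1 of 3 metal and iron genes to pass.

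Among regulators and metabolic genes, PPARg (0.98 ± 0.30), thyroid hormone receptor alpha (0.91 ± 0.23, adjusted p = 0.0156) and CYP_2 (0.93 ± 0.30, adjusted p = 0.0461) were higher in the inner harbour. CYP_2 bears the name of a cytochrome P450 family of monooxygenases, and it was the 1 of 8 phase I genes to pass. Both tested genes named pgi were higher, pgi-1 by 0.68 ± 0.19 and pgi-2 by 0.93 ± 0.27. Pyruvate kinase, a glycolytic enzyme, was lower (-0.61 ± 0.21, adjusted p = 0.0498), so the carbohydrate list had 2 higher, 1 lower and 2 not past of 5. IGF_II, a growth factor, had -1.13 ± 0.37, and VEGF, which drives vessel growth, -0.93 ± 0.24. Lower values were also called for Inf-kappa-ba (-0.94 ± 0.21), INFkappaB? (-0.82 ± 0.20, 3 of 4 probes), PCD8 (-0.72 ± 0.16), CYP7 (-0.90 ± 0.29, 1 of 4 probes), AOX (-0.85 ± 0.28, 1 of 4), Ef1-alpha (-0.74 ± 0.25, 1 of 5) and leukotriene A4 hydrolase (-0.73 ± 0.24, 2 of 4). Leukotriene A4 hydrolase was well above background in 4 of 6 inner and 6 of 6 outer fish, so its size rests in part on background signals. None of the 6 phase II genes, 8 mitochondrial genes or 8 cell cycle genes tested passed.

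In all, 25 probes (7 genes) were higher and 44 (17 genes) lower in the inner harbour at the first sampling, and 127 had an unadjusted p under 0.05. This split turned with the scaling of the arrays, from 17 higher and 24 lower (quantile) and 15 and 21 (deposited values) to 25 and 10 (array median and, added later, the median over detected probes), 32 and 5 (75th percentile over detected probes) and 12 and 7 (spike-ins). It was 11 and 18 with normexp, and of the 22 genes named by the rule only heme oxygenase was called under all 7 other scalings, while none changed its direction. The count of 69 fell to 14 with only the compared groups in the fit and to 18 with the sample number as a block. It also fell to between 33 and 44 when inner fish 3, 7 or 8 or outer fish 3 or 4 was left out. Only 8 of the 22 genes kept their call whichever fish was left out: heme oxygenase, choriogenin L, thyroid hormone receptor alpha, alpha-2-macroglobulin, Inf-kappa-ba, INFkappaB?, VEGF and PCD8. All 22 genes kept their sign within each of the 3 slides, and with slide as a block 18 stayed past the threshold (CYP_2, AOX, Ef1-alpha and leukotriene A4 hydrolase did not). The 22 genes were chosen by their calls on these same arrays, so agreement in sign within slides is no independent check.

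**Figure D1:**
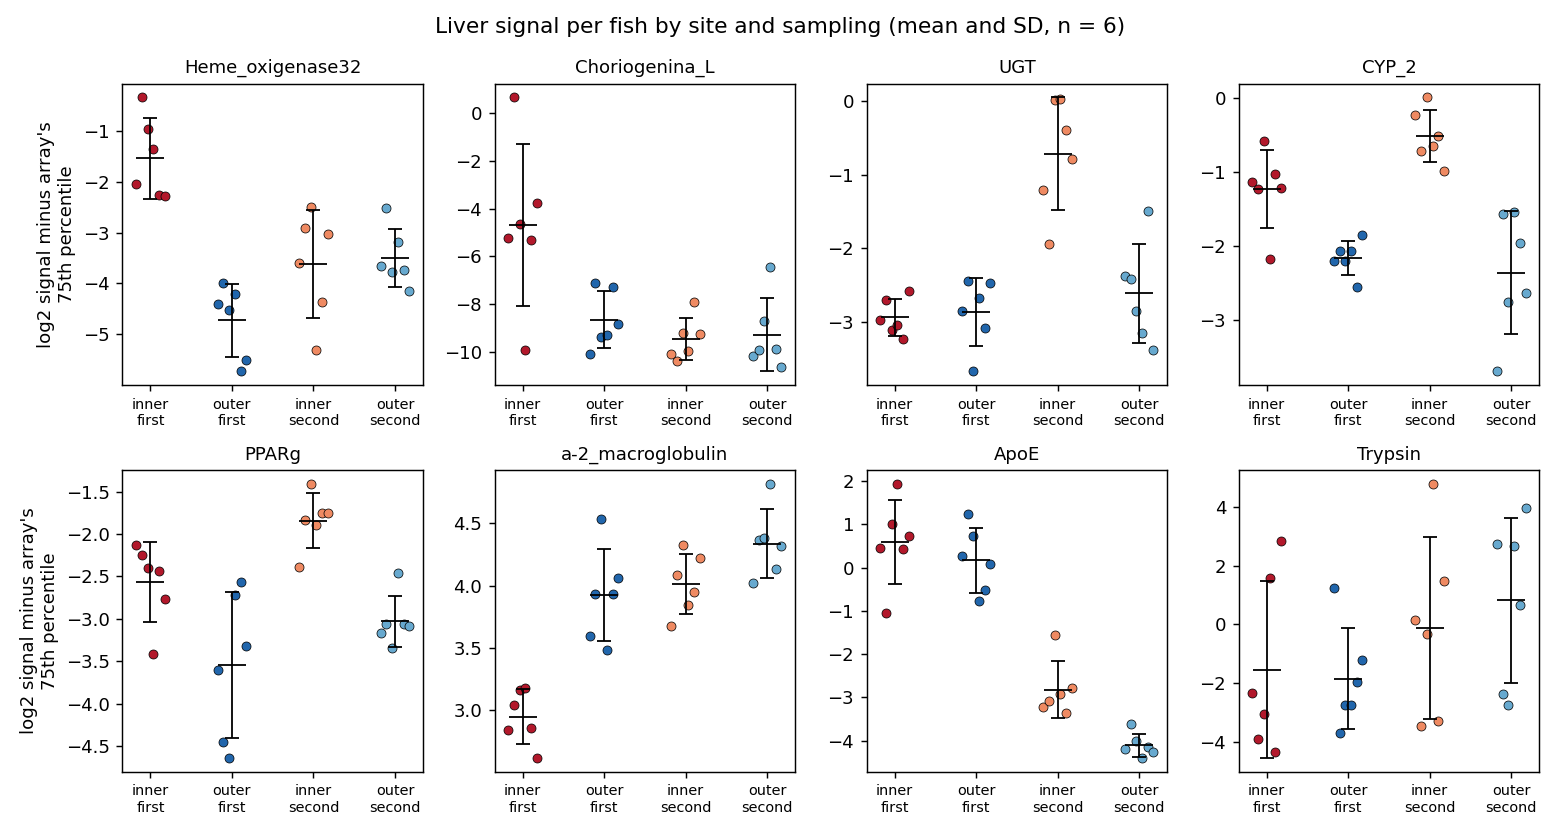
Log2 signal minus the array's 75th percentile (vertical axis) for single genes in each of the 24 fish, by site and sampling (horizontal axis); points are fish, and bars give the mean and SD of 6 fish. Heme oxygenase of all 6 inner fish lies above all 6 outer fish at the first sampling, and CYP_2 does so at the second.

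At the second sampling the same comparison asks how the sites differed later in the caging. UGT, named for the glucuronosyltransferases that conjugate foreign compounds and hormones, was 3.74-fold higher in the inner harbour (log2 difference 1.90 ± 0.32, n = 6 and 6, adjusted p = 3.25e-04). CYP_2 was 3.60-fold higher (1.85 ± 0.30, adjusted p = 3.25e-04), with no overlap between the groups. GST, a glutathione conjugation enzyme, was higher by 0.85 ± 0.20 (adjusted p = 0.00749) and epoxide hydrolase 1 by 0.85 ± 0.26 (adjusted p = 0.0296). CYP3 had 0.51 ± 0.17, with 2 of 4 probes called.

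Of the 8 phase I genes 2 rose, 0 fell and 6 did not pass, with 4 past when adjusted over the list alone, and of the 6 phase II genes 2 rose and 4 did not pass, with 2 past over the list alone. The phase I list reached a camera adjusted p of 0.0831, and adjusted p = 0.561 with an estimated correlation. It passed with quantile normalization (adjusted p = 0.0300) and with the deposited values (adjusted p = 0.0154). CYP_2 and UGT came into their lists only by spellings matched after the results had been seen, and with the fixed name patterns alone no list passed under any of these 3 scalings.

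In the peroxisome list 2 of 4 genes were higher in the inner harbour and 2 did not pass. The higher ones were catalase, which breaks down hydrogen peroxide (0.94 ± 0.24, adjusted p = 0.0140, 4 of 4 probes), and PPARg (1.19 ± 0.30, adjusted p = 0.0123). ApoE, a lipoprotein component, was higher by 1.28 ± 0.39, and CYP7, a family holding bile acid synthesis enzymes, by 1.15 ± 0.29. The rule also named MF1 (1.23 ± 0.33), XDh (1.22 ± 0.40), IGFI (0.82 ± 0.19), thyroid hormone receptor alpha (0.78 ± 0.23, 3 of 4 probes), ki-Ras (0.77 ± 0.22) and pyruvate kinase (0.67 ± 0.21). MF1 and thyroid hormone receptor alpha were each well above background in 4 of 6 outer fish, so their sizes rest in part on background signals. The remaining called gene was PCD8 (0.49 ± 0.16, adjusted p = 0.0494). None of 9 acute phase and immune genes, 3 heat shock genes, 3 metal and iron genes, 8 mitochondrial genes or 4 estrogen responsive genes passed. Adjusted over the list alone, 1 of the metal and iron genes passed and none of the others. Hepcidin, the iron-regulating peptide hormone, had the largest difference among these (-2.10 ± 0.80, adjusted p = 0.101).

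Altogether 61 probes in 16 genes were higher and 0 lower in the inner harbour in limma's test, with 96 at an unadjusted p under 0.05. The absence of lower calls depends on the scaling: 11 higher and 14 lower probes were called with quantile normalization, 10 and 8 with the deposited values, and 8 and 38 with the added median over detected probes. The split was 38 and 2 with the array median, 57 and 0 with the 75th percentile over detected probes, 88 and 0 with spike-ins and 43 and 0 with normexp, and only UGT and CYP_2 of the 15 genes named by the rule were called under all 7. Without inner fish 3 the count was 31. UGT, CYP_2, PPARg, CYP7, catalase, GST and IGFI (7 of 15) kept their call whichever fish was left out. All 15 genes were higher in the inner harbour within each slide and past the threshold with slide as a block. They too were chosen by their calls on these same arrays, so agreement within slides is no independent check.

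**Figure D2:**
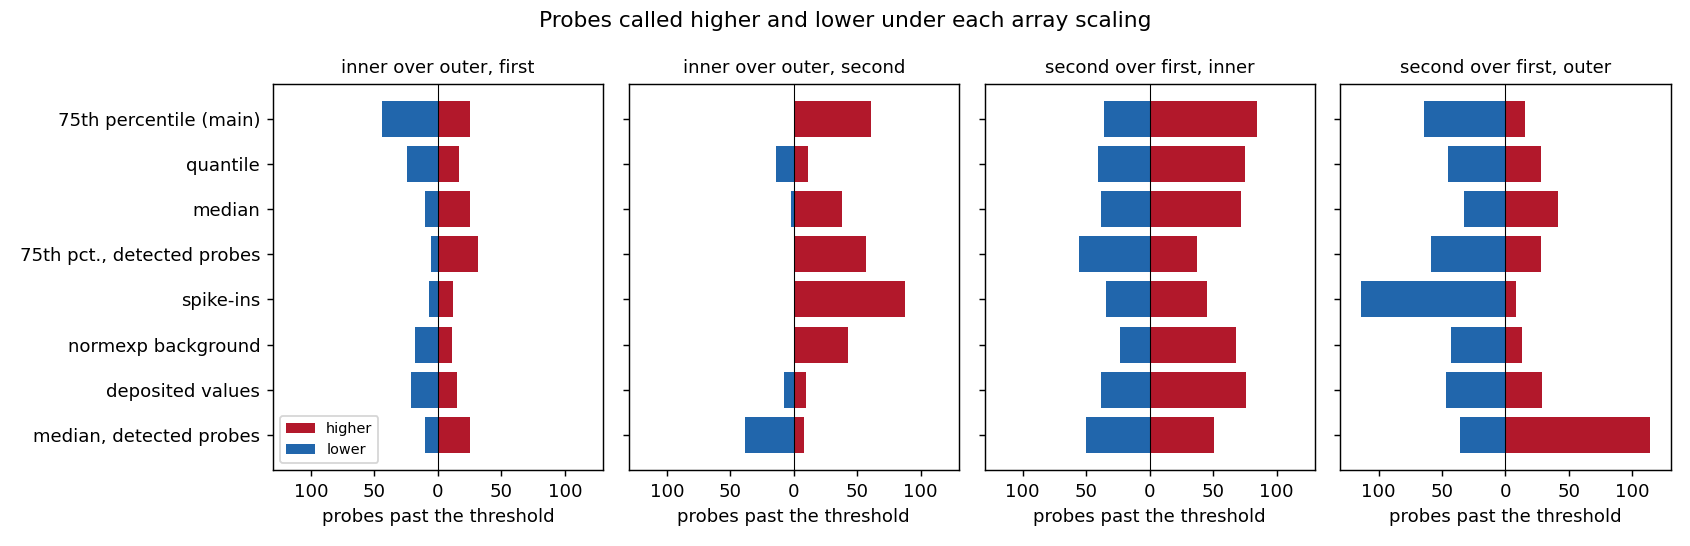
Number of probes past the threshold (horizontal axis, higher in the inner harbour or at the second sampling to the right, lower to the left) under each scaling of the arrays (vertical axis), for the site and sampling contrasts. At the second sampling the main scaling calls 61 higher and 0 lower probes, and the deposited values call 10 and 8.

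Genes commonly used as pollution markers were followed whatever their p, each with its brightest tested probe and the range over its probes. CYP1A1, the monooxygenase induced through the aryl hydrocarbon receptor, had 0 of 4 probes past the threshold at either sampling. Its difference was -0.38 at the first sampling (95% interval -0.97 to 0.20) and 0.44 at the second (-0.15 to 1.02). The 4 probes ran from -0.76 to -0.38 at the first, with a smallest adjusted p of 0.158, and from 0.43 to 0.46 at the second. Metallothionein (MT), which binds metals, had 0.29 ± 0.36 and then 0.70 ± 0.36 (probes 0.29 to 0.36 and 0.70 to 0.77), again with 0 of 4 probes past. At the second sampling, however, each of the 4 MT probes was called higher in the inner harbour under 1 of the 7 other scalings. At the first sampling catalase had -0.42 ± 0.24 (probes -0.43 to -0.40) and GST -0.12 ± 0.20 (-0.25 to -0.12). Neither passed on any probe, and the GST probe had the opposite sign under 4 other scalings. HSP70 had 0.42 ± 0.21 at the second sampling (probes 0.36 to 0.43) with 0 of 4 probes past. Choriogenin L had -0.17 ± 1.08 there (probes -0.53 to -0.12), with 0 of 6 inner and 1 of 6 outer fish well above background, so no size is resolved, and a positive sign under 2 scalings. The vitellogenin-like VgC had 1.78 ± 0.86 (adjusted p = 0.186) and -0.25 ± 0.86 (adjusted p = 0.962, positive under spike-in scaling). With an array left out the first difference ranged from 1.09 to 2.59, and VgC was called in 1 of 12 such fits. Its 3 probes ran from 1.69 to 1.78 and from -0.25 to -0.18, with 0 past. VTG-A, VTG-B, Cyp1, CYP1_C and CYP1Bb were not well above background on enough arrays to be tested.

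Over the mean of both samplings, 27 probes in 7 genes were higher and 8 probes in 3 genes lower in the inner harbour, with 106 at an unadjusted p under 0.05. The higher genes were heme oxygenase (1.53 ± 0.31), CYP_2 (1.39 ± 0.21, adjusted p = 2.44e-04), PPARg (1.08 ± 0.21), XDh (0.97 ± 0.28), ApoE (0.95 ± 0.28, 3 of 4 probes), UGT (0.91 ± 0.23) and thyroid hormone receptor alpha (0.84 ± 0.16). The last was well above background in 4 of 6 outer fish at the second sampling. Lower were alpha-2-macroglobulin (-0.65 ± 0.12), INFkappaB? (-0.60 ± 0.14, 3 of 4 probes) and Inf-kappa-ba (-0.60 ± 0.15). Heme oxygenase differed at the first sampling (3.18), with group means of -3.62 (inner) and -3.50 (outer) at the second. UGT differed at the second (1.90), with group means of -2.94 (inner) and -2.87 (outer) at the first. The named probes of heme oxygenase, CYP_2 and PPARg were called under all 7 other scalings. The split was 28 and 33 with quantile normalization, 31 and 26 with the deposited values, 37 and 0 with spike-ins and 27 and 15 with the added median.

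No relation between the site differences of both samplings was detected across the 476 probes, which are not independent. Pearson's r was -0.09 (exact permutation p = 0.677), Spearman's rho -0.05 (p = 0.727, exact permutation), and 45.0% of the probes had the same sign (exact permutation p = 0.530). Relabelled sites gave r between -0.41 and 0.41 in 95% of cases, so a moderate relation would not have been seen. 11 probes, of PPARg, CYP_2 and thyroid hormone receptor alpha, were higher at both samplings, against 3.20 for independent lists of 25 and 61 probes. Another 9, of pyruvate kinase, PCD8 and CYP7, were lower at the first and higher at the second, against 5.64 for independent lists of 44 and 61. Probes of 1 gene move together, so these counts stand for few genes and independent lists are only a rough reference.

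**Figure D3:**
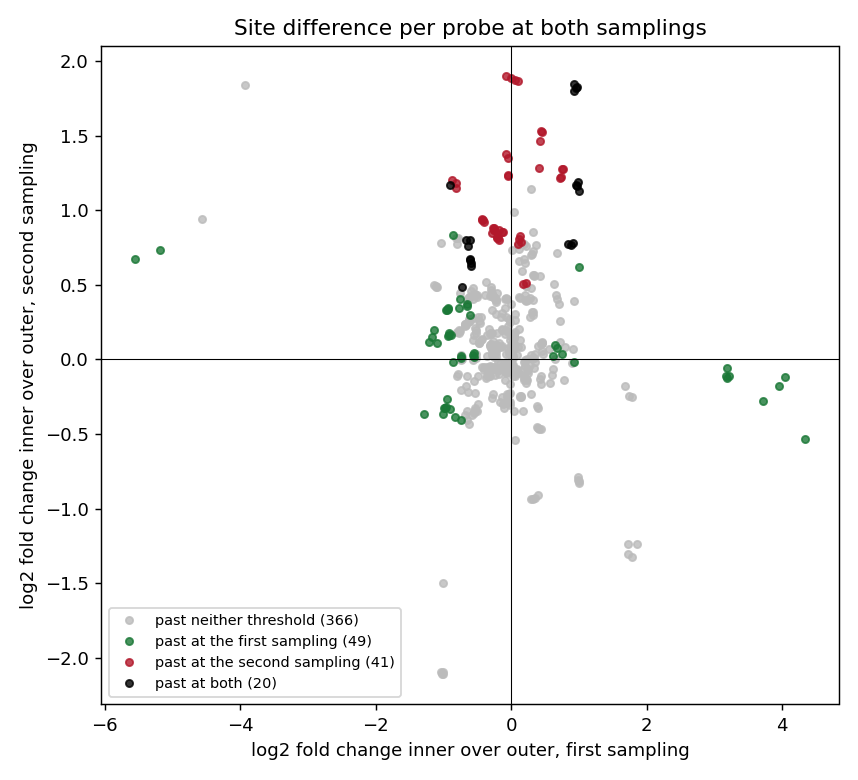
Log2 difference inner over outer harbour of each of the 476 tested probes at the first (horizontal axis) and second sampling (vertical axis); colours give where the probe was past the threshold. 20 probes passed at both samplings, 49 at the first alone and 41 at the second alone.

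The comparison of samplings asks how expression changed over the caging at each site, and under the main scaling it called more probes than the comparison of sites. In the inner harbour CYP7 rose 8.92-fold (3.16 ± 0.29 log2 units, adjusted p = 1.11e-08) and GST 6.84-fold (2.77 ± 0.20, adjusted p = 1.21e-10). UGT rose by 2.23 ± 0.32 and Cu-Zn_SOD, the superoxide dismutase of the cytosol, by 1.84 ± 0.19. ApoE fell by 3.41 (SE 0.39, adjusted p = 2.49e-07), the protease cathepsin L by 2.28 (SE 0.39), CYP_scc-24 by 2.22 (SE 0.46) and heme oxygenase by 2.07 (SE 0.44). Choriogenin L was lower at the second sampling, when 0 of 6 inner fish were well above background (adjusted p = 0.00179). The group means gave a lower bound of 12.5-fold, which leaves out the spread between fish (SD 3.39 at the first sampling). The 95% interval of the log2 difference, -6.98 to -2.53, reaches smaller falls than that bound. Only 5 of 6 inner fish were well above background at the first sampling, so the size of the fall is not resolved.

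By list, 4 of 8 phase I genes were called higher at the second sampling in the inner harbour, and 6 passed when adjusted over the list alone. The 4 called were Cyp2N (1.52 ± 0.42), CYP1A1 (1.03 ± 0.28, adjusted p = 0.00887), CYP3 (0.66 ± 0.17) and AHRR, the repressor of the aryl hydrocarbon receptor. AHRR has 1 tested probe, well above background in 1 of 6 inner fish at the first sampling and 2 of 6 at the second. Its call therefore rests largely on background signals, and neither a rise nor its size is resolved. Of 6 phase II genes 4 rose, and 5 passed over the list alone, among them the transporters ABC-b1 (0.97 ± 0.33, 1 of 4 probes) and ABCC2 (0.85 ± 0.27). Of 5 antioxidant genes 2 rose and 1 fell, and the rest did not pass. Neither biotransformation list passed camera (both adjusted p = 0.209, and adjusted p = 0.561 with an estimated correlation). The rule also named alcohol_DHVI (1.52 ± 0.24), VEGF (1.29 ± 0.24), IGF_II (1.18 ± 0.37), DACD1 (1.13 ± 0.28), alpha-2-macroglobulin (1.07 ± 0.18) and cyclin G1 (0.90 ± 0.19) as higher. Lower were PPARa (-1.51 ± 0.51, 3 of 4 probes), phosphoenolpyruvate carboxykinase (-1.01 ± 0.36, 2 of 4), pgi-2, FHC (-0.76 ± 0.23) and RXR (-0.51 ± 0.18). PPARa was well above background in 6 of 6 inner fish and then in 4 of 6, so its size rests in part on background signals. The fall of pgi-2 has no resolved size, as it was well above background in 6 of 6 fish and then in 2 of 6. C3 probes disagreed, with 2 of 4 lower (-0.73 ± 0.23) and the others at 0.23 without passing.

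In the outer harbour GST rose 3.48-fold (1.80 ± 0.20, adjusted p = 3.91e-07), Cu-Zn_SOD 2.97-fold (1.57 ± 0.19) and CYP7 2.29-fold (1.20 ± 0.29). ApoE was 19.4-fold lower at the second sampling (-4.28 ± 0.39, adjusted p = 1.48e-08). In the peroxisome list 2 of 4 genes fell, catalase by 1.48 (SE 0.24, adjusted p = 1.13e-04) and the peroxisomal membrane protein PMP70 by 1.00 (SE 0.24). Phosphoenolpyruvate carboxykinase, a gluconeogenic enzyme, fell by 1.54 (SE 0.36), cathepsin L by 1.42 (SE 0.39) and epoxide hydrolase 1 by 1.03 (SE 0.26). Further lower genes were AOX (-1.43 ± 0.28), MF1 (-1.09 ± 0.33), pyruvate kinase (-0.79 ± 0.21), Ef1-alpha (-0.77 ± 0.25), PCD8 (-0.75 ± 0.16) and HSP70 (-0.71 ± 0.21), and UE2a fell by 1.00 (SE 0.28). MF1 was well above background in 6 of 6 outer fish and then in 4 of 6, so its size rests in part on background signals. ABCC3 and leukotriene A4 hydrolase (1 of 4 probes) were also called lower, without a resolved size. They were well above background in 5 of 6 and 6 of 6 outer fish at the first sampling and in 1 of 6 each at the second. Heme oxygenase (1.28 ± 0.44), TBTbp (0.69 ± 0.22) and peroxiredoxin (0.49 ± 0.16) were higher, each on 1 of 4 probes. No phase I gene rose, and 1 of 8 fell.

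Counts between samplings were 85 higher and 36 lower in the inner harbour (182 at an unadjusted p under 0.05) and 15 and 64 in the outer harbour (130). Of these calls 14 higher probes were shared between sites, against 2.68 for independent lists, and 14 lower probes, against 4.84. Probes of 1 gene move together (median correlation 0.987), so the shared probes are not independent and stand for fewer genes. All 4 probes of GST, Cu-Zn_SOD and CYP7 are among the higher ones, and all 4 of ApoE and cathepsin L among the lower. The sites share no array in these contrasts. The inner split was 37 and 56 with the 75th percentile over detected probes, 45 and 34 with spike-ins and 51 and 50 with the added median. The outer split was 28 and 45 with quantile normalization, 41 and 33 with the array median, 28 and 59 with the 75th percentile over detected probes, 8 and 114 with spike-ins, 29 and 47 with the deposited values and 114 and 36 with the added median. GST, Cu-Zn_SOD and ApoE were called at both sites under all 7 other scalings, as were UGT, CYP7, cathepsin L and heme oxygenase in the inner harbour and catalase, AOX, PMP70 and phosphoenolpyruvate carboxykinase in the outer.

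The site difference itself changed between samplings for 58 probes, 53 upward in 15 genes and 5 downward in 2 genes, with 144 at an unadjusted p under 0.05. Heme oxygenase moved from higher in the inner harbour to no called difference (change -3.29 ± 0.62, adjusted p = 0.00162). So did choriogenin L, on 1 of 4 probes (adjusted p = 0.0330). On that probe 5 of 6 inner and 1 of 6 outer fish were well above background at the first sampling, and 0 of 6 and 1 of 6 at the second, so the size of its change is not resolved. The largest upward changes were in UGT (1.98 ± 0.45), CYP7 (1.96 ± 0.42) and AOX (1.57 ± 0.40). Catalase changed by 1.35 ± 0.34, GST by 0.98 ± 0.28, HSP70 by 1.02 ± 0.30 and transferrin by 1.28 ± 0.37. Of the other upward genes, HSC70 was called on 3 of 4 probes, and MF1 and AHR2 on 1 of 4 each. Of the 17 named probes only that of heme oxygenase was called under all 7 other scalings, as were 2 further UGT probes. The split was 6 and 8 with quantile normalization, 7 and 6 with the deposited values, 19 and 11 with the array median, 18 and 9 with the 75th percentile over detected probes and 10 and 21 with the added median.

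As a marker of exocrine pancreas, which lies within the liver of many fish, trypsin varied over 9.13 log2 units among the 24 fish and passed in no contrast. Its difference was 0.32 ± 1.46 between sites at the first sampling and -0.94 ± 1.46 at the second. Between samplings it was 1.42 ± 1.46 in the inner and 2.68 ± 1.46 in the outer harbour. The lists of erythrocyte and muscle markers had 0 tested genes. Among 3 reference genes, 18S_rRNA was not called in any site or sampling contrast, Beta-actin rose in the inner harbour between samplings (0.56 ± 0.20, adjusted p = 0.0391), and Ef1-alpha fell in the outer harbour. Between sites, 0 of 4 ribosomal and translation genes, 0 of 2 protein degradation genes and 0 of 1 plasma protein gene passed on their brightest probe at either sampling. Adjusted over the list alone, 1 ribosomal and translation gene and 1 reference gene passed at the first. Of 3 lipid genes ApoE alone passed, at the second sampling.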

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

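The tests of trypsin and the splits of the arrays were chosen before their results were seen. The tests of scaling, slide, array row and column and of a single fish were chosen only after the result was seen.

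The first pattern is the excess of higher over lower probes in the inner harbour at the second sampling (61 and 0). With the deposited values 55.6% of the called probes were higher, and with quantile normalization 44.0%, which is consistent with array scaling as a source of the one-sided split. With the array median it was 95%, and it stayed at 100% with the 75th percentile over detected probes, spike-ins and normexp, so which scaling gives the right balance is not settled. Of the probes called on the other slides (20, 30 and 8), 100% were higher within the slide left out, but 8 are too few for that test to decide. Every slide holds 2 arrays of each group, so a shift shared by all arrays of a slide cancels from the site difference. This balance argues against such a shift as the source of the split. Slide as a block (68 probes higher and 0 lower) adds nothing on direction, because it leaves every difference as it was and changes only the standard errors. Pancreas tissue in the dissected liver is argued against by the trypsin level as a covariate, with which the called probes kept 95.5% of their median difference. The site remains open as a biological explanation for UGT and CYP_2, which were called under all 7 other scalings. Whether it also adds to the one-sided count was not settled.

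The second pattern is the higher heme oxygenase and choriogenin L in the inner harbour at the first sampling. Heme oxygenase was higher by 3.00 log2 units in the slide with the smallest difference, and the sites change columns on 1 slide, which argues against slide or array column. For choriogenin L, 4 inner fish besides the highest (fish 3) were well above background and above all outer fish, which argues against a single fish as the whole cause. On the probe named Choriogenina_L, inner fish 3 lay at 0.64 and inner fish 5 at -9.92 (log2 signal minus the array's 75th percentile). A response to the site may be involved, as a hypothesis. An effect of the cage, the sex of the fish or their origin was not tested.

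The third pattern is the set of probes that changed the same way between samplings at both sites (14 higher and 14 lower). At the lowest (spike-ins), 60.7% of them were called the same way at both sites under another scaling, so array scaling stays open for part of the set. Trypsin itself rose between samplings by 1.42 log2 units in the inner and 2.68 in the outer harbour, without passing. With trypsin as a covariate the probes kept 99.7% of their median absolute change, which argues against pancreas tissue. Because 0 arrays of the first sampling lie in the second row of a slide, sampling and array row cannot be told apart. Time in the cage and age also change with sampling, season and feeding may do so, and all stay open.

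Other splits of the same arrays were counted with 100 splits for each contrast, and in each the real split alone (1 of 100) gave as many calls. The real and highest other counts were 69 and 27 (sites, first sampling), 61 and 9 (sites, second), 35 and 30 (sites, mean), 121 and 44 (samplings, inner), 79 and 36 (samplings, outer) and 58 and 38 (change of the site difference). With 100 splits a share below 1 of 100 cannot be resolved, so under the main scaling chance is argued against and not excluded. The margin was narrow for the mean of both samplings. There 30 probes were called at the lowest with an array left out, no more than in the highest other split.

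In 14 of 228 sets of 6 fish over 57 named genes 1 fish lay far from the others, against 11.4 by chance at 1 in 20. The values are distances from the median of the other fish in the group, in log2 units. In the inner harbour at the first sampling these were pgi-1 (-0.74) and PPARa (-0.93) in fish 3, catalase (1.26) in fish 4, IGFI (-0.75) and Cyp2N (-2.88) in fish 5, and CYP_scc-24 (-2.40) in fish 8. MHC_II (6.03) also stood out in fish 8, but this is no measured size, as the other inner fish were not well above background. At the second sampling ApoE (1.54) and XDh (1.40) stood out in inner fish 3. In the outer harbour they were the immunoglobulin (1.69) in fish 5 and PMP70 (1.15) in fish 4 at the first sampling. At the second they were PPARg (0.62) in fish 5 and MF1 (-1.74) and cyclin G1 (-0.84) in fish 2.

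For 17 genes the site difference itself changed between samplings in limma's test of the interaction, as the difference at the second minus that at the first sampling. The change was 1.98 for UGT, 1.96 for CYP7, 1.57 for AOX, 1.45 for MF1 (1 of 4 probes), 1.35 for catalase, 1.29 for pyruvate kinase, 1.28 for transferrin and 1.20 for PCD8. The MF1 probe was well above background in 4 of 6 outer fish at the second sampling. The change was 1.15 for HSC70 (3 of 4 probes), 1.14 for epoxide hydrolase 1, 1.09 for VEGF, 1.04 for AHR2 (1 of 4 probes), 1.02 for HSP70, 1.01 for IGFI and 0.98 for GST. Heme oxygenase had -3.29. Choriogenin L had -4.87 on 1 of 4 probes, which is not a measured size, since 0 of 6 inner and 1 of 6 outer fish were well above background on it at the second sampling. Upward changes may in part follow the scaling, since quantile normalization called 14 probes and the deposited values 13, against 58.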

How the results depend on the processing

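The median over detected probes, the trypsin covariate and lists from name patterns alone were chosen after the data had been seen. Of the 111 named calls, 107 held with slide as a block, 105 with array weights, 102 with trypsin as a covariate, 94 with all probes tested and 70 with the replicate block. With only the groups compared, 61 of 84 held. Under the scalings between 61 (deposited values) and 76 (array median, spike-ins) held, 62 with quantile normalization and 63 with the median over detected probes. 1 turned its sign without passing: leukotriene A4 hydrolase between samplings in the outer harbour was 0.048 with normexp. The median over all tested probes moved by more than 0.1 log2 units in several contrasts, by 0.31 with spike-ins and -0.41 with the median over detected probes for sites at the second sampling, and by -0.41 and 0.34 for samplings in the outer harbour. For sites at the first sampling it moved by 0.25 with the 75th percentile over detected probes, for samplings in the inner harbour by -0.32 with the same, and for the change of the site difference by -0.27 with the array median and -0.56 with the median over detected probes.

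Probes called between sites at the first sampling (69) numbered 41 with quantile normalization, 35 with the array median, 37 with the 75th percentile over detected probes, 19 with spike-ins, 29 with normexp, 36 with the deposited values and 35 with the median over detected probes. They numbered 41 with all probes tested, 14 with only the groups compared, and 0, 0 and 9 within the 3 slides, each of which has 2 fish a group. At the second sampling (61) the counts were 25 with quantile normalization, 40 with the array median, 18 with the deposited values, and 0, 4 and 4 within slides. For the mean of both (35) they were 61 with quantile normalization, 55 with the 75th percentile over detected probes, 23 with normexp, 57 with the deposited values and 57 with array weights. Between samplings, 79 probes were called in the inner harbour with spike-ins (against 121). In the outer harbour (79) it was 122 with spike-ins, 150 with the median over detected probes and 129 with all probes tested. The site difference changed (58) for 14 probes with quantile normalization, 30 with the array median, 27 with the 75th percentile over detected probes, 13 with the deposited values, 31 with the median over detected probes and 93 with array weights. The causes were not tested, except that the filter and the within-slide fits change the number of probes or fish.

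With each array left out in turn, the calls ranged from 33 to 80 between sites at the first sampling (44 without inner fish 3, 33 without inner fish 7, 38 without inner fish 8, 33 without outer fish 3 and 38 without outer fish 4). They ranged from 31 (without inner fish 3) to 67 at the second sampling and from 30 to 43 for the mean of both. Ranges were 94 to 125 for samplings in the inner harbour, 60 to 80 in the outer harbour and 47 to 73 for the change of the site difference. Named genes that kept their call whichever array was left out were 8 of 22, 7 of 15, 8 of 10, 17 of 26, 13 of 21 and 11 of 17 in the same order, and no called gene turned its sign.

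The sample numbers did not pair the samples: over 29 pairs the correlation of deviations ran from -0.36 to 0.39, 7 were over 0.1, and in 4 the own number matched best. With the replicate block, 18 probes were called between sites at the first sampling and 39 at the second, and 33, 108, 68 and 41 in the other contrasts in the order above. No gene list passed, and 1 did with quantile normalization and 1 with the deposited values (phase I, second sampling). The correlation of site differences stayed between -0.09 and -0.00028 in all settings tried.

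Genes that were not called turned their sign as follows. GST between sites at the first sampling was 0.013 with the array median, 0.13 with the 75th percentile over detected probes, 0.020 with the deposited values and 0.034 with the median over detected probes. Choriogenin L at the second sampling was 0.021 with quantile normalization, 0.13 with spike-ins and 0.22 with array weights, and ranged from -0.49 to 0.39 with an array left out. VgC was 0.054 with spike-ins, 0.16 with the replicate block, and ranged from -0.53 to 0.14 with an array left out. Dim signal limits choriogenin L, well above background in few fish of the second sampling.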

Other observations

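Hepcidin, an iron-regulating hormone, had differences of -1.03 ± 0.80 (first) and -2.10 ± 0.80 (second) between sites and fell by 1.95 (SE 0.80) between samplings in the inner harbour, none past the threshold. Mhc2, a second gene with a class II histocompatibility name, had -1.04 ± 0.67 at the first sampling, in the direction of MHC_II and without passing. CYP1A1 rose between samplings in the inner harbour by 1.03 ± 0.28 while its change in the outer harbour was 0.21 ± 0.28, and the difference of these changes was 0.82 ± 0.40 (limma adjusted p = 0.165).

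Choriogenin L and VgC, both named for estrogen-responsive liver products, were compared over the 24 fish after group means had been removed. This was the only relation computed, chosen after the data had been seen. Pearson's r was 0.71 (permutation p = 0.0122) and Spearman's rho 0.36 (permutation p = 0.107). Choriogenin L was well above background in only 8 of the 24 fish, so both values rest largely on background signals. Without the 2 fish farthest from the median r was 0.24 (permutation p = 0.342), so the relation rests on those fish. Within slides r was 0.89, 0.83 and -0.45.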
